A study of Rattus norvegicus with 8 samples.

How the data were processed

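RNA from the cortex of 4 tMCAO and 4 sham-operated Sprague Dawley rats, taken at 24 h from a 4 mm section on the operated side, was profiled on two-colour Agilent arrays. Per the labels' protocols, total RNA was column-purified with DNase treatment, amplified from 100 ng in 2 rounds of reverse transcription and in vitro transcription, and labelled with Cy5 for the animal and Cy3 for a pool of sham cortex RNA that was on every array. The dyes were not swapped, so a dye effect on a gene is the same on all 8 arrays and cancels between the groups. The labels name the animals of a group as biological replicates 1 to 4. Their source names also number each animal, without saying what the number stands for, and it was not used here. The numbers of sham replicate 4 and tMCAO replicate 4 lie well above those of the other animals. No slide, scan date or batch was used here, since none stands in the labels or tables.

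The deposited table holds 2 intensities per reporter and array, normalized by the authors in a way not given in the sources used here; the submitters' processing notes name Agilent Feature Extraction 8.5.1.1. The deposited intensities have the same median in both channels of an array to within 0.01, and 99.4% of them are whole multiples of 0.01 (to a tolerance of a millionth of that step). The authors' p-value per reporter and array is in the same deposited table, and the error model behind it is not given in the sources used here. The authors' log10 ratios in the series' value table equal the log10 of intensity 2 over intensity 1 to within 0.005, and their median is 0 on each of the 8 arrays. Which intensity is the pool was checked on the values: over 11327 reporters with a mean log2 intensity 1 above -2, intensity 1 correlated across sham and tMCAO arrays at r = 0.970 to 0.988 and intensity 2 at r = 0.850 to 0.954, so intensity 1 was taken as the Cy3 pool and intensity 2 as the Cy5 animal. Within sham arrays intensity 1 correlated at r = 0.994 or more and within tMCAO arrays at 0.991 or more. No background values were used here.

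The deposited log10 ratios were multiplied by the log2 of 10 (3.322) with no further normalization. Of 23609 reporters, 16536 had a symbol in the table; 14081 matched a current symbol of the rat RefSeq table (assembly GRCr8, used for names only), 2114 an older synonym, and 315 neither, which kept the table's name. A further 51 reporters, with no symbol or with a date in its place, were named through their accession. That left 23 whose symbols had been turned into dates and 7025 with no name, and these last 2 sets, 7048 reporters, entered only the test by reporter. No coordinates are given because the tables hold none. Reporters of a gene were averaged, which gave 11019 genes, 3564 of those tested having more than 1 reporter; 52 genes had reporters called in opposite directions, Jun, Timp2 and the ribosomal gene Rps25 among them. Of all cells, 640 (0.339%) were blank. Genes with a ratio on at least 3 arrays of each group were tested, 10962 in all, which left out 57.

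The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 6 residual degrees of freedom) and Benjamini-Hochberg adjustment, with a call at an adjusted p under 0.05. The 34 gene lists were tested with camera at a preset correlation of 0.01, on genes with a value on all 8 arrays and lists with at least 3 members, adjusted over the lists; camera with an estimated correlation and fry were run beside it. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, and 1 alternative was added afterwards. The rule names the 10 largest positive and 10 largest negative log2 differences among called genes whose 4 tMCAO values lie apart from the 4 sham values, passing over uninformative symbols, and for each list the 2 called members that moved most in the list's main direction and the 1 called member that moved most the other way, or, with no called member, the one with the smallest p; this gave 83 genes, 3 of which are not reported here. Members beyond the rule are marked as named after their values were seen. The exceptions are members that bound a range, were not tested or had reporters called in opposite directions. Fcrls, a microglia marker, was matched to Fcrl2 through a synonym.

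The fit was tested on simulated ratios of 10962 genes with the residual spread of each gene and 50 genes changed at each of 4 sizes. It called 34.0% of genes changed by 0.5, 76.0% of those changed by 1, 98.0% of those changed by 2 and 100% of those changed by 3 on the log2 scale, with 7 false among 161 calls. Far fewer genes were changed there than the 37% called in the data. The simulated noise was independent between genes and had the same spread in both groups. These shares therefore check the fit and do not give the power or false calls of the comparison itself. Alternatives covered the scaling of ratios, loess within arrays, the value table, dim or incomplete genes, the choice of reporter, thresholds, the variance model, array weights, an unmoderated test, tMCAO ratios against 0, the replicate number as a block and each array left out. A different background correction was not run, because the table gives no background. The number of arrays limits the precision. In sham cortex 21.9% of the genes tested had a mean intensity under 0.1, where a rounding step of 0.01 is 0.14 or more on the log2 scale. Plots were drawn with matplotlib 3.10.9.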

Results

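Gene expression was measured in the cortex of Sprague Dawley rats 24 h after transient middle cerebral artery occlusion (tMCAO), a stroke model in which a major artery of the brain is blocked for a time and then reopened, and in the cortex of sham-operated rats. The tissue came from a 4 mm section on the operated side. Each of 8 two-colour Agilent arrays carried the RNA of 1 animal in the Cy5 channel, 4 with tMCAO and 4 with sham surgery, and the same pool of sham cortex RNA in the Cy3 channel. The values are log2 ratios of the animal over the pool, so that a gene at the level of the pool has a ratio of 0. Between 23434 and 23565 of 23609 reporters had a ratio on an array, and 10962 named genes had enough values to be compared. The number of arrays limits the precision, and each group had n = 4. A log2 difference is the tMCAO mean minus the sham mean and is followed by its standard error (SE) from limma. Adjusted p-values of genes are limma's, two-sided, over all genes tested.

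The comparison asked which genes were higher or lower in the cortex after tMCAO than after sham surgery. Most measured genes of reactive astrocytes and macrophages were higher and most pan-neuronal genes were lower when tested gene by gene, while the tests of these lists as wholes depended on the correlation assumed between genes and were not passed when it was estimated (adjusted p = 0.213, 0.213 and 0.265). In all, 2005 genes were higher and 2053 were lower, together 37.0% of the genes tested. The difference was at least 1 on the log2 scale for 510 of the higher and 341 of the lower genes. The 4 tMCAO values lay wholly above or below the 4 sham values for 3791 genes, or 34.6%, where chance gives 2.86%. Quantile normalization between arrays lowered the counts to 1249 higher and 1105 lower genes.

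Serpina3n, an acute phase protease inhibitor made by reactive astrocytes, had the largest rise among genes with separate groups, a log2 difference of 4.63 ± 0.58 (SE, adjusted p = 0.00215); its ratio to the pool averaged 3.44 in tMCAO animals and -1.19 in sham animals. Slpi, an inhibitor of leukocyte proteases, differed by 4.16 ± 0.62, and Spp1, which encodes the secreted protein osteopontin, by 4.07 ± 0.64. Without sham replicate 2 the difference of Spp1 was 3.36. Its intensity in tMCAO replicate 1, 22.37, was close to the highest of that channel, 22.43, so that the top of the scale limits how well this rise is measured. Lbp, which encodes the lipopolysaccharide-binding protein, differed by 3.93 ± 0.49. Fcgr2b, an Fc receptor of myeloid and B cells, differed by 3.81 ± 0.36 and Esm1, a proteoglycan secreted by endothelial cells, by 3.78 ± 0.52. The differences of the calcium-binding protein gene S100a4 (3.40 ± 0.33), the proteoglycan gene Sdc1 (3.35 ± 0.47), the kininogen gene Kng1 (3.34 ± 0.37) and Gpnmb, a glycoprotein of phagocytes (3.27 ± 0.39), complete the 10 largest, and the adjusted p of each of the 10 was at most 0.00358. Rats carry several similar kininogen genes and Fc receptor genes, and each of these 2 genes was read by 1 reporter, so that the member measured is uncertain. In sham cortex Esm1 had a mean intensity of 0.0225, Kng1 of 0.050, Lbp of 0.085, Serpina3n of 0.1025 (0.04 in replicate 2) and Slpi of 0.115. These are low against the 0.01 step to which the deposited intensities were rounded, which makes their differences imprecise.

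The largest fall with separate groups was that of Olr59, annotated as an olfactory receptor, with a log2 difference of -2.50 ± 0.56 (SE, adjusted p = 0.0103), and of -3.16 without tMCAO replicate 4. The activity-regulated transcription factor gene Egr4 fell by 2.33 on the log2 scale (SE 0.54), by 1.71 without tMCAO replicate 1, and its tMCAO ratio of -1.90 was not called against 0. The mean intensity of Egr4 in sham cortex was 24.48, where the highest of that channel on the sham arrays was 26.4 to 27.6. The top of the scale therefore limits how well this fall is measured. Vsnl1, a neuronal calcium sensor, fell by 2.29 (SE 0.42). Gabrd, the delta subunit of GABA-A receptors, had a difference of -2.24 ± 0.39. Abra, an actin-binding protein, and Nrgn, the postsynaptic calmodulin-binding protein neurogranin, each differed by -2.16, with SEs of 0.34 and 0.35. The peroxisomal transporter gene Abcd2 (-2.15 ± 0.45) and the neural transcription factor genes Pou3f2 (-2.13 ± 0.49) and Neurod1 (-2.05 ± 0.52, and -2.64 without tMCAO replicate 4) also fell, and the adjusted p of each of these 9 falls was at most 0.0167. Of the 4 tMCAO animals, replicate 4 had the ratio nearest to the sham mean for 9 of these 9 genes and for 8 of the 10 highest genes.

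**Figure D1:**
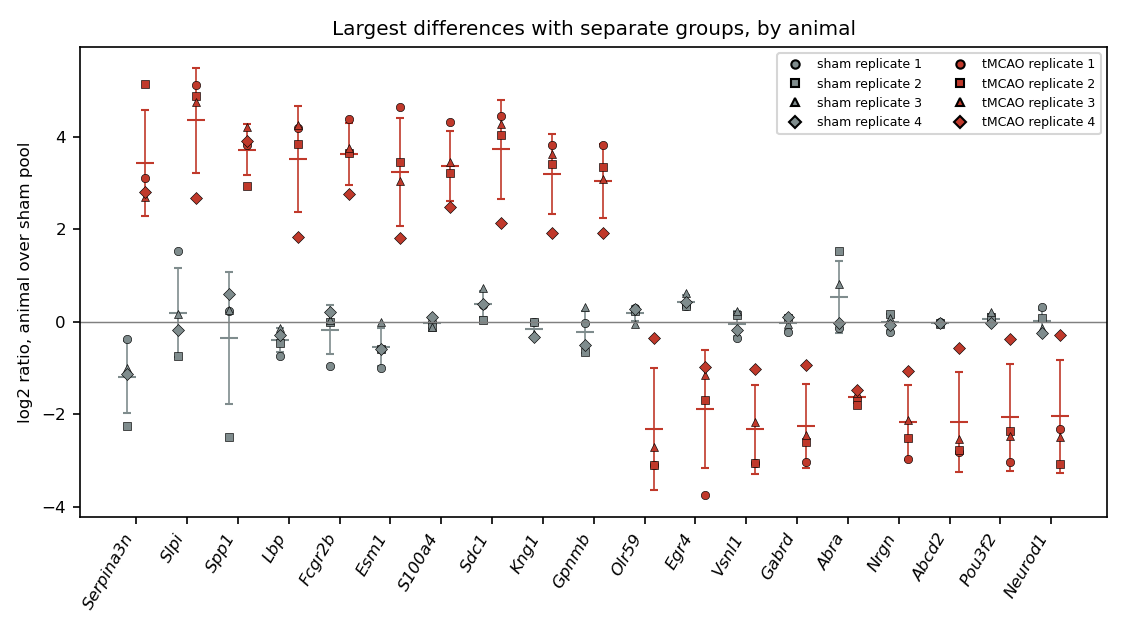
Log2 ratio of each animal over the sham pool (y axis) for the 10 highest and 9 of the 10 lowest genes whose groups lie apart (x axis). Grey symbols are the 4 sham animals and red symbols the 4 tMCAO animals, with a symbol shape per replicate number, and horizontal lines and bars give the mean and SD; Serpina3n averaged 3.44 in tMCAO and -1.19 in sham animals, and Olr59 averaged -2.32 and 0.19.

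Of 34 gene lists fixed in advance, camera, which tests whether a list moved against all other genes and here assumed a correlation of 0.01 between members, called 16 higher and 8 lower after tMCAO. With a correlation estimated per list it called 0 of the 34 lists. The lowest adjusted p was then 0.21, and 7 of the 24 had an unadjusted p under 0.05. The test fry, which asks whether a list's genes move on balance in a single direction, called 21 of the 24. Of the 35 splits of the 8 arrays into 4 and 4, the real one included, 6 gave at least 24 called lists. The 5 others each kept 3 of the 4 tMCAO arrays together, so they could carry much of a real difference. The set tests below are therefore given with both p-values, and the counts of members rest on the test of each gene.

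**Figure D2:**
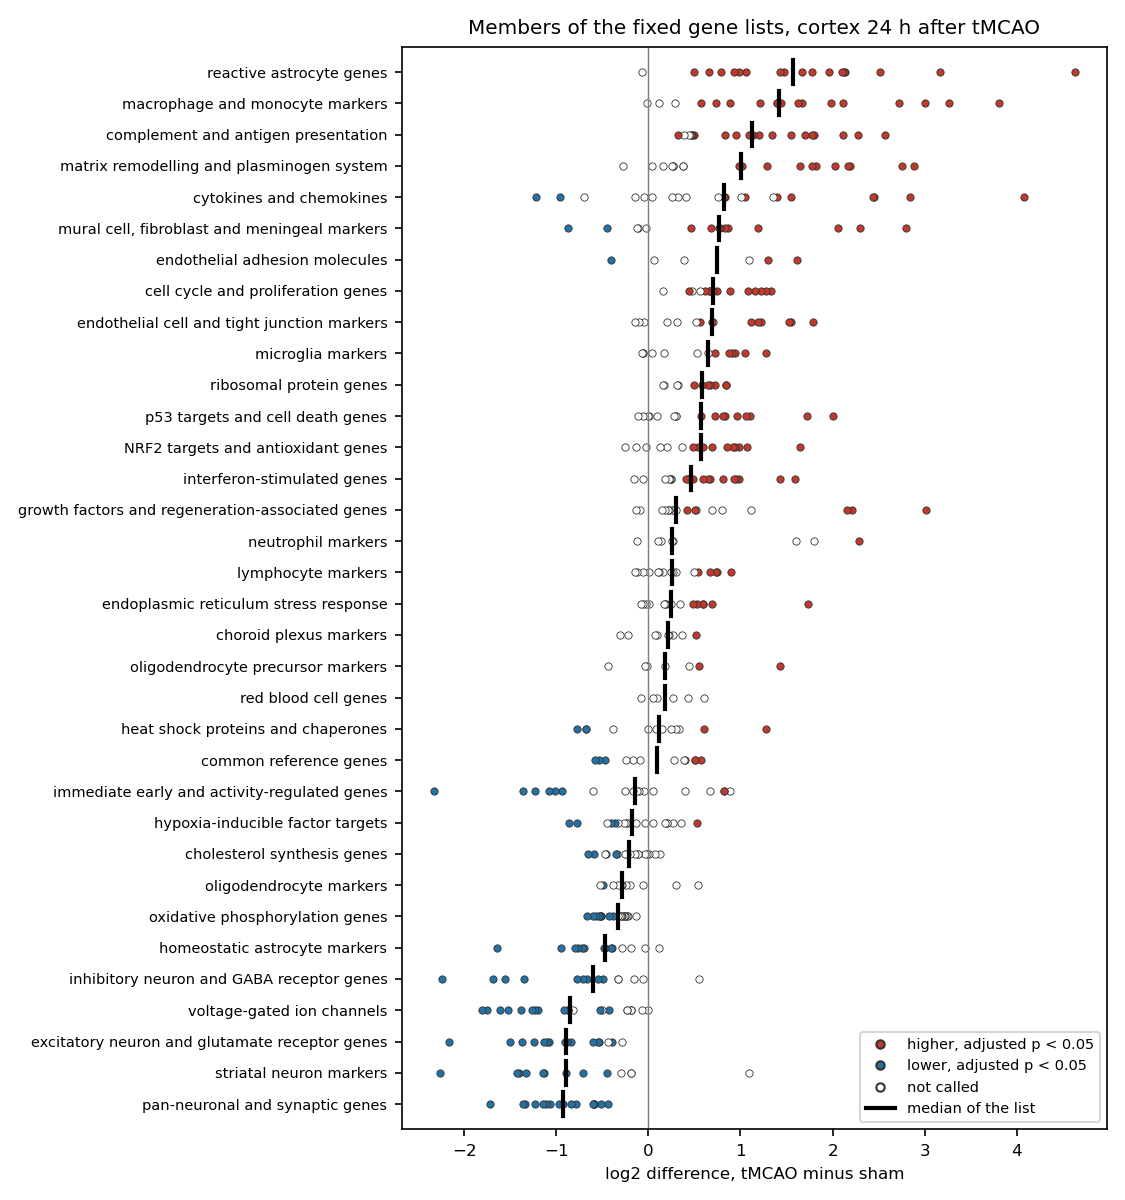
Log2 difference between tMCAO and sham cortex (x axis) of every measured member of the 34 fixed gene lists (y axis, ordered by median). Each circle is a gene, filled red or blue where it was higher or lower at an adjusted p under 0.05 and open otherwise, and black bars are list medians, which ran from -0.93 for pan-neuronal genes to 1.57 for reactive astrocyte genes.

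Most reactive astrocyte genes and some microglia markers were higher. Of 18 measured genes of the reactive astrocyte list, 17 were higher, and 17 when adjusted over the list alone. Cd14 is also counted in the macrophage list, and Tnfrsf1a in the p53 and cell death list. The RNA came from whole cortex, so the cells behind a rise cannot be told from these values. Their median log2 difference was 1.57 (camera adjusted p = 9.2e-10; adjusted p = 0.213 with an estimated correlation). Besides Serpina3n the largest rise was that of Cd44, a receptor for hyaluronan, at 3.17 ± 0.32. Markers of homeostatic astrocytes went the other way: 10 of 14 were lower, also 10 when adjusted over the list alone, and none was higher (camera adjusted p = 0.000314; adjusted p = 0.213 with an estimated correlation). Gjb6, which encodes the gap junction protein connexin 30, fell by 1.64 on the log2 scale (SE 0.19) and the glycolytic enzyme gene Aldoc by 0.95 (SE 0.10). Of 13 microglia markers, 6 were higher, 6 when adjusted over the list alone (camera adjusted p = 0.00795; adjusted p = 0.366 with an estimated correlation); the list was not called when tMCAO ratios were set against 0. Among them were the fractalkine receptor gene Cx3cr1 (1.28 ± 0.25) and the lysosomal membrane gene Laptm5 (1.05 ± 0.26). Cx3cr1 was dim, with a mean intensity of 0.085 in sham cortex, so its difference is imprecise.

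Most genes of macrophages, complement and antigen presentation were higher. In the macrophage and monocyte list 15 of 18 genes were higher, 15 when adjusted over the list alone. The median log2 difference was 1.42 (camera adjusted p = 2.07e-08; adjusted p = 0.213 with an estimated correlation). Fcgr2b and Gpnmb led the list. In the complement and antigen presentation list 18 of 20 genes were higher, 18 when adjusted over the list alone (camera adjusted p = 9.2e-10; adjusted p = 0.213 with an estimated correlation). Cd74, the invariant chain of class II antigen presentation, differed by 2.57 ± 0.29 and C5ar1, the receptor for the complement fragment C5a, by 2.27 ± 0.33. Of 20 interferon-stimulated genes, 12 were higher, 12 when adjusted over the list alone (camera adjusted p = 2.3e-05; adjusted p = 0.213 with an estimated correlation). Oas1a, an antiviral enzyme, differed by 1.59 ± 0.22 and the immunoproteasome subunit gene Psmb8 by 1.42 ± 0.18. The beta-globin gene Hbb, a marker of red blood cells, had log2 ratios of 1.37 and 0.90 in tMCAO replicates 1 and 2 and of -0.09 and -0.12 in replicates 3 and 4, and the sham arrays reached up to 0.15. The macrophage list had medians of 1.86, 1.31, 1.77 and 0.90 above the sham mean in tMCAO replicates 1 to 4.

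Of 21 cytokine and chemokine genes, 9 were higher and 2 were lower, and 9 and 3 when adjusted over the list alone (camera adjusted p = 0.00569; adjusted p = 0.496 with an estimated correlation, and 0.0505 by fry). The list was not called after quantile normalization. Its median was 1.21, 1.08, 0.76 and 0.04 above the sham mean in tMCAO replicates 1 to 4, and -0.12 to 0.19 in sham animals. After Spp1 the largest rise was that of the monocyte chemoattractant gene Ccl7, at 2.85 ± 0.26. The chemokine gene Ccl3 fell by 1.22 on the log2 scale (SE 0.24), of which its tMCAO ratio to the pool made up -0.61, not called against 0, and the other lower member was the related Ccl4 with -0.96, named after its value was seen. In the neutrophil list only the decoy interleukin-1 receptor gene Il1r2 was called among 8 measured genes, at 2.28 ± 0.49, 1 when adjusted over the list alone, and at 1.39 without a call after quantile normalization. Il1r2 was dim, with mean intensities of 0.1125 in tMCAO and 0.0225 in sham cortex, so its difference is imprecise. The list was not called (camera adjusted p = 0.192). Of 16 lymphocyte markers 5 were higher, and 4 when adjusted over the list alone, with Cd2 at 0.89 ± 0.26 and Cd8a at 0.75 ± 0.20, both surface proteins of T cells. The list was called (camera adjusted p = 0.0213), but not with an estimated correlation (adjusted p = 0.488), by fry (0.0555), after quantile normalization or without tMCAO replicate 2 (0.052). Leaving out any 1 sham array ended the call of Cd2 (adjusted p = 0.055 to 0.065), and leaving out sham replicate 2, tMCAO replicate 1 or tMCAO replicate 2 ended that of Cd8a (0.052 to 0.055), as did quantile normalization (log2 difference 0.53) and the replicate block. Cd8a was also dim, with a mean intensity of 0.0475 in sham cortex. Red blood cell genes held 0 called members of 6, 0 when adjusted over the list alone, and were not called as a list (camera adjusted p = 0.374); Hbb had the smallest p among them, at 0.61 ± 0.33 (adjusted p = 0.172).

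Many vascular and matrix genes were higher. In the matrix and plasminogen list 12 of 19 genes were higher, 13 when adjusted over the list alone (camera adjusted p = 6.48e-06; adjusted p = 0.265 with an estimated correlation). The metalloprotease inhibitor gene Timp1 differed by 2.75 ± 0.31. Of 15 endothelial and tight junction markers 8 were higher, 9 when adjusted over the list alone (camera adjusted p = 0.00295; adjusted p = 0.393 with an estimated correlation). The VEGF receptor gene Kdr (1.79 ± 0.35) and the sialomucin gene Emcn (1.55 ± 0.30) differed most. The endothelial list's median was 0.09 above the sham mean in tMCAO replicate 4. It was 0.73 to 1.08 in replicates 1 to 3 and at most 0.05 in sham animals. Among 15 mural cell, fibroblast and meningeal markers 10 were higher and 2 lower, the same numbers when adjusted over the list alone (camera adjusted p = 0.0106; adjusted p = 0.393 with an estimated correlation), and the list was not called for tMCAO ratios against 0. This list's median was 0.11 in tMCAO replicate 4 and 0.69 to 0.96 in replicates 1 to 3. The aminopeptidase gene Anpep differed by 2.80 ± 0.36 and the smooth muscle gene Tagln by 2.29 ± 0.27, while the pericyte marker Rgs5 fell by 0.87 (SE 0.15) and Slc22a6, named after its value was seen, had a difference of -0.45. Of 6 endothelial adhesion molecules Icam2 (1.61 ± 0.30) and Sele (1.30 ± 0.34) were higher and Vcam1 was lower (-0.41 ± 0.13), 2 and 1 also when adjusted over the list alone. As a list they were not called (camera adjusted p = 0.192). Their median was -0.27 in tMCAO replicate 4 and 0.65 to 1.30 in replicates 1 to 3. The call of Sele was lost without sham replicate 1 or 2 (adjusted p = 0.052), and that of Vcam1 without sham replicate 2, 3 or 4 or tMCAO replicate 2 or 3 (0.069 to 0.089). Quantile normalization also ended the call of Sele (log2 difference 0.67), and the replicate block and ratios against 0 that of Vcam1. Icam2 and Sele were dim in sham cortex, with mean intensities of 0.0575 and 0.0375, so their differences are imprecise.

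Some growth factor and stress genes were higher. Of 19 growth factor and regeneration-associated genes 5 were higher, 3 when adjusted over the list alone (camera adjusted p = 0.00569; adjusted p = 0.393 with an estimated correlation). Quantile normalization between arrays ended the call of this list. The neuropeptide gene Gal (3.02 ± 0.28) and Sprr1a, a gene induced in injured neurons (2.22 ± 0.49), were among them. The growth factor list's median was 0.41, 0.73, 0.57 and 0.04 above the sham mean in tMCAO replicates 1 to 4. Sham animals had -0.09 to 0.13. Of 16 targets of the oxidative stress regulator NRF2 and antioxidant genes 10 were higher, 11 when adjusted over the list alone (camera adjusted p = 5.33e-05; adjusted p = 0.213 with an estimated correlation). Osgin1 differed by 1.64 ± 0.20 and the peroxiredoxin gene Prdx1 by 1.07 ± 0.17. Of 17 p53 targets and cell death genes 10 were higher, 10 when adjusted over the list alone (camera adjusted p = 0.000196; adjusted p = 0.247 with an estimated correlation). Tnfrsf12a, the TWEAK receptor, differed by 2.00 ± 0.32 and the inflammatory caspase gene Casp1 by 1.72 ± 0.25. Casp1 was dim, with a mean intensity of 0.0325 in sham cortex, so its difference is imprecise. Of 15 endoplasmic reticulum stress genes 6 were higher, 7 when adjusted over the list alone (camera adjusted p = 0.00295; adjusted p = 0.213 with an estimated correlation), and quantile normalization ended this list's call too. The pseudokinase gene Trib3 differed by 1.73 ± 0.18 and Ddit3, which encodes the transcription factor CHOP, by 0.69 ± 0.10. After quantile normalization the differences of Prdx1 (0.845), Trib3 (0.71) and Ddit3 (0.35) were no longer called.

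3 lists linked to acute stress were not called as lists. Among 12 heat shock genes and chaperones Hspb1 (1.27 ± 0.16) and Hspb8 (0.60 ± 0.13) were higher and Dnajb1 (-0.78 ± 0.11) and Bag3 (-0.67, named after its value was seen) were lower, 2 and 2 also when adjusted over the list alone (camera adjusted p = 0.578). The ratio of Bag3 to the pool averaged 0.15 in tMCAO and 0.82 in sham animals, and that of Dnajb1 -0.36 and 0.41. After quantile normalization Hspb1 (0.27) and Hspb8 (0.17) were no longer called. The inducible heat shock gene Hspa1a had no ratio on any tMCAO array and an intensity of 25.6 on the 3 sham arrays that read it, near the top of the scale, and was not tested. Of 18 immediate early genes Klf4 was higher (0.82 ± 0.17) and 6 were lower, 2 and 6 when adjusted over the list alone (camera adjusted p = 0.313, and 0.00848 for a lower list after quantile normalization, which ended the call of Klf4 at a log2 difference of 0.35). Besides Egr4 the largest fall was that of the nuclear receptor gene Nr4a1, by 1.36 (SE 0.20). Of 18 targets of hypoxia-inducible factors the lactate dehydrogenase gene Ldha was higher (0.52 ± 0.12) and 4 were lower, 1 and 4 also when adjusted over the list alone (camera adjusted p = 0.442). The lower ones were Bnip3, a mitochondrial regulator of cell death and autophagy (-0.86 ± 0.27), Ndrg1 (-0.78 ± 0.11) and, named after their values were seen, Egln3 (-0.41) and Slc2a3 (-0.36). Leaving out any 1 array other than tMCAO replicate 4 ended the call of Bnip3 (adjusted p = 0.072 to 0.094), as did quantile normalization (log2 difference -0.39) and the replicate block, and the brightest reporter ended that of Ndrg1 (-0.50).

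Most members of the neuronal lists were lower. Of 17 pan-neuronal and synaptic genes 17 were lower, also when adjusted over the list alone. The median log2 difference was -0.93 (camera adjusted p = 7.59e-07; adjusted p = 0.265 with an estimated correlation). Differences ran from -0.44 for Vamp2 to -1.72 for the synaptic vesicle gene Rab3a (SE 0.33), and the neurofilament gene Nefh had -1.36 ± 0.33. Of 16 excitatory neuron and glutamate receptor genes 14 were lower, 15 when adjusted over the list alone (camera adjusted p = 6.48e-06; adjusted p = 0.265 with an estimated correlation). Nrgn fell most, followed by the AMPA receptor gene Gria2 (-1.51 ± 0.35). Of 14 inhibitory neuron and GABA receptor genes 9 were lower, 9 when adjusted over the list alone (camera adjusted p = 0.00323; adjusted p = 0.213 with an estimated correlation). Gabrd, given above, was 1 of them. Of 22 voltage-gated ion channel genes 13 were lower, 16 when adjusted over the list alone (camera adjusted p = 6.48e-06; adjusted p = 0.247 with an estimated correlation). The sodium channel genes Scn8a (-1.81 ± 0.37) and Scn1a (-1.75 ± 0.36) fell most. Of 13 markers of striatal neurons, several of which cortical neurons also express, 9 were lower, with 9 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.000314; adjusted p = 0.213 with an estimated correlation). Rasd2 was 1 of them (-1.43 ± 0.37). Its call was lost without sham replicate 1 or tMCAO replicate 2 (adjusted p = 0.050 and 0.053).

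Markers of oligodendrocytes and of the choroid plexus showed few calls. Of 11 oligodendrocyte markers only Ugt8, an enzyme of myelin lipid synthesis, was called, at -0.50 ± 0.12, 1 also when adjusted over the list alone, and not after quantile normalization (-0.36). That list was not called (camera adjusted p = 0.237). Its median from the sham mean was -0.61 in tMCAO replicate 4 and -0.17 to 0.01 in replicates 1 to 3. Sham animals had -0.10 to 0.14. Of 7 precursor markers the proteoglycan gene Vcan (1.43 ± 0.30) and the transcription factor gene Sox10 (0.55 ± 0.16) were higher, 2 also when adjusted over the list alone (camera adjusted p = 0.237). The call of Sox10 was lost without any 1 array other than tMCAO replicate 4 (adjusted p = 0.063 to 0.078) and after quantile normalization (log2 difference 0.33). Of 9 choroid plexus markers only the water channel gene Aqp1 was called, at 0.52 ± 0.15, and 0 when adjusted over the list alone (camera adjusted p = 0.481). In tMCAO replicate 1 the choroid plexus list had a median of 0.55 above the sham mean, against -0.23 to 0.04 in the other tMCAO animals. Named after their values were seen, Sostdc1 had a ratio of 2.98 there (-0.86 to -0.39 in the other tMCAO animals), Ttr of 1.94 and Enpp2 of 1.09. Aqp1 was dim, with a mean intensity of 0.035 in tMCAO and 0.0325 in sham cortex, its tMCAO ratios averaged -0.02, and its call was lost without sham replicate 2, 3 or 4 or tMCAO replicate 2 or 3 (adjusted p = 0.057 to 0.062).

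Many cell cycle and ribosomal protein genes were higher, and some genes of mitochondrial respiration were lower. Of 16 cell cycle genes 13 were higher, 15 when adjusted over the list alone (camera adjusted p = 5e-07; adjusted p = 0.213 with an estimated correlation). The replication helicase genes Mcm2 and Mcm5 differed by 1.33 ± 0.20 and 1.27 ± 0.13. Mcm2 was dim, with a mean intensity of 0.045 in sham cortex, so its difference is imprecise. Of 11 ribosomal protein genes 7 were higher, 9 when adjusted over the list alone (camera adjusted p = 3.82e-05; adjusted p = 0.213 with an estimated correlation). Rpl10a and Rpl19 each differed by 0.84, with SEs of 0.13 and 0.11. Of 19 oxidative phosphorylation genes 10 were lower, 12 when adjusted over the list alone (camera adjusted p = 0.000387; adjusted p = 0.393 with an estimated correlation). Sdha (-0.67 ± 0.15) and Uqcrc2 (-0.60 ± 0.18), genes of complexes II and III, fell most. The call of Uqcrc2 was lost without any 1 sham array or without tMCAO replicate 1 or 3 (adjusted p = 0.050 to 0.074), with the replicate block, with the brightest reporter (log2 difference -0.22) and after quantile normalization (-0.27), which ended that of Sdha too (-0.38). Of 18 cholesterol synthesis genes 4 were lower, 4 when adjusted over the list alone, led by Mvk (-0.65 ± 0.10) and Fdps (-0.59 ± 0.08). The list's call (camera adjusted p = 0.0213; adjusted p = 0.488 with an estimated correlation, and 0.0542 by fry) was lost without tMCAO replicate 4 (adjusted p = 0.37), against 0 and with the brightest reporter of each gene, which also ended that of Fdps (log2 difference -0.09).

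Genes often used as references did not hold a common level. Of 12, 4 were higher, among them Polr2a (0.57 ± 0.18), Gusb (0.50 ± 0.10) and, named after its value was seen, Actb (0.50). Ywhaz (-0.58 ± 0.10) and, likewise named afterwards, Gapdh (-0.53) and Hprt1 (-0.47) were lower; adjusted over the list alone 5 were higher and 3 lower. The list was not called (camera adjusted p = 0.497). The call of Polr2a was lost without any 1 array other than tMCAO replicate 4 (adjusted p = 0.063 to 0.096), against 0 and after quantile normalization (log2 difference 0.33).

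The tMCAO animals differed in how far their profiles departed from sham. The SD of the log2 ratios over reporters was 0.741, 0.690, 0.614 and 0.368 in tMCAO replicates 1 to 4, against 0.230 to 0.258 in sham animals. Across genes, which are not independent replicates, the ratios correlated at r = 0.89 to 0.92 among tMCAO replicates 1 to 3 and at r = 0.62 to 0.67 between replicate 4 and the others. Over 689 genes called at least 1 higher without replicate 4, the slope of its changes on the mean of the other 3 animals was 0.44, with a range of 0.411 to 0.469 when genes were resampled, and over 525 genes at least 1 lower it was 0.324 (0.305 to 0.343). 92.6% of the former and 93.7% of the latter moved in the same direction in replicate 4. The authors' deposited table gives a ratio p-value under 0.01 to 8330, 7928, 6827 and 2751 reporters in tMCAO replicates 1 to 4. It gives 443 to 643 such reporters in sham animals. Without tMCAO replicate 4, 2710 genes were higher and 2943 lower.

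**Figure D3:**
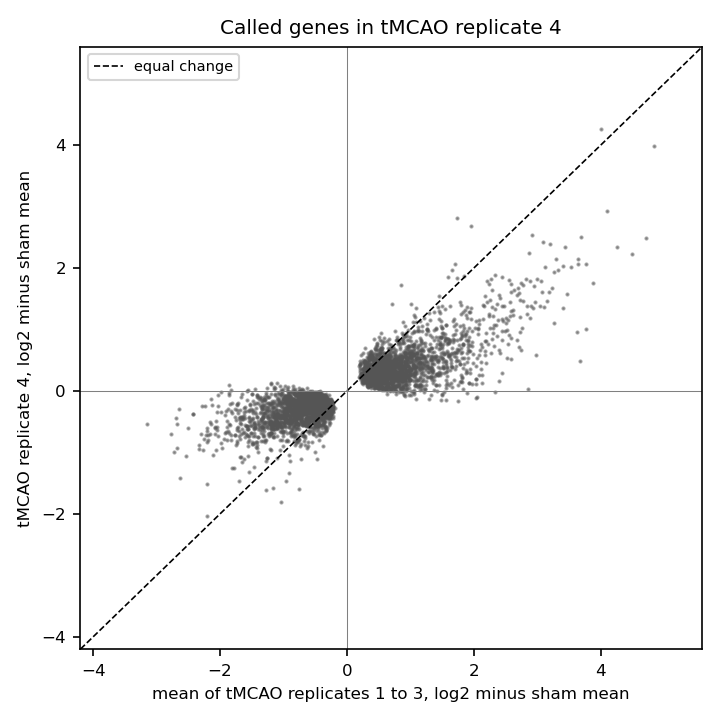
Change in tMCAO replicate 4 (y axis, log2 ratio minus the sham mean) against the mean change in tMCAO replicates 1 to 3 (x axis, same unit) for 4037 called genes with a value on all 8 arrays, a point per gene. Most points lie between the horizontal axis and the dashed line of equal change. The genes drawn were called with replicate 4 included, which favours genes that moved the same way there. Slopes of 0.44 and 0.324 were taken over another set, 689 genes at least 1 higher and 525 at least 1 lower, called without replicate 4.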

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

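The tests of the smaller changes in tMCAO replicate 4 and of blood were chosen after the results were seen; those of blank cells and of other splits were chosen before.

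Of 160 sets of 4 values (80 named genes in 2 groups), 19 held a sample far from the other 3, where chance gives about 1 in 20, or 8. The sets come from the same animals and mostly from called genes, so they are not independent and the 8 is a rough guide. The sample was tMCAO replicate 4 in 10 of them. Its log2 ratio was below the other tMCAO animals for Slpi (2.68 against 4.75 to 5.12), Lbp (1.83 against 3.85 to 4.25), Tnfrsf12a (1.20 against 2.62 to 2.71), Cx3cr1 (0.42 against 1.35 to 1.53), Il1r2 (1.00 against 2.58 to 2.91) and Oas1a (0.82 against 1.72 to 1.83). It was less negative for Olr59 (-0.35 against -3.10 to -2.71), Abcd2 (-0.57 against -2.82 to -2.53), Rgs5 (-0.40 against -1.01 to -0.91) and Dnajb1 (-0.15 against -0.46 to -0.41).

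The smaller changes in tMCAO replicate 4 were set against 3 explanations. A compressed range of this array is argued against by the SD of its log2 intensity 2 over reporters, 2.27, within the 2.25 to 2.30 of the sham arrays. It was below the 2.31 to 2.45 of the other tMCAO arrays, but by far less than slopes of 0.44 and 0.324 would need. This array did have the most blank cells, 175 against 44 to 93, and the lowest maximum of the 8 arrays in both channels (26.1 and 21.29), so another fault of the array stays open. A sham animal under a tMCAO label is argued against by the median change of the 1220 genes called at a log2 difference of at least 1 without this array, which was 0.53 in their called direction, against -0.03 to 0.03 for each sham animal set against the other 3. Dilution of the injured tissue by a single share of uninjured tissue is argued against as the whole account: the median share of the change kept was 0.346 over 1214 genes (0.274 over higher and 0.451 over lower genes; this share is on the scale of folds, and the slopes on the log2 scale were in the opposite order), but 5 of 17 lists lay outside the 95% range of random sets of their size, among them reactive astrocyte genes at 0.596 (range 0.195 to 0.514). Against sets matched for direction 5 lists lay outside, all of them above, and 3 lists (immediate early, reactive astrocyte and cell cycle genes) lay outside both ranges; endothelial markers at 0.106 lay below the first range (0.138 to 0.599) but within the matched one (0.102 to 0.538). Members of a list vary together, so these ranges are too narrow to some degree. Most but not all lists changed less in replicate 4. Its medians from the sham mean were -0.61 for oligodendrocyte, -0.43 for cholesterol, 0.38 for heat shock and -0.67 for immediate early genes. Those of tMCAO replicates 1 to 3 were -0.17 to 0.01, -0.11 to -0.04, -0.09 to 0.20 and -0.42 to 0.05. A smaller response therefore does not describe every list, and the cause was not tested. A smaller injury in this animal, with dilution as a part of it, stays open and untested, since no infarct size was used here.

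Blood left in the tissue was weighed for the rise of immune genes, because Hbb was raised in tMCAO replicates 1 and 2 alone. Replicates 3 and 4 had Hbb ratios no higher than the sham arrays, and the lower of their 2 macrophage list medians was 0.903 above the sham mean, against at most 0.02 (SD 0.01) on the sham arrays. That argues against blood as the whole account of the macrophage rise; cells that had entered the tissue and changes in resident cells cannot be separated by these values and remain untested.

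Of the other sets, 4 concerned sham replicate 2. Spp1 had a log2 ratio of -2.48 there, against 0.24 to 0.59 in the other sham animals, Klf4 0.35 against 0.11 to 0.12, Casp1 -0.42 against 0 and Emcn 0.34 against -0.81 to -0.68. Cx3cr1 was 0.26 in sham replicate 4 against -0.19 to -0.17, Gusb was -0.17 in sham replicate 3 against 0, and Aqp1 was -0.42 in sham replicate 1 against -0.58. Cd2 was 1.83 in tMCAO replicate 1 against 0.58 to 0.75 in the other tMCAO animals. Serpina3n was 5.15 in tMCAO replicate 2 against 2.70 to 3.11; its intensity there was 26.28 in the animal's channel and 0.74 in the pool's, where the pool read 0.19 to 0.26 on the other arrays. Casp1, Cx3cr1, Emcn, Gusb, Klf4 and Aqp1 were dim in sham cortex, with mean intensities of 0.0325 to 0.135, where rounding alone moves a ratio in visible steps.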

How the results depend on the processing

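The camera run that combined an estimated correlation with leaving out an array was chosen after the data were seen; the other alternatives were planned. Genes higher and lower numbered 1249 and 1105 after quantile normalization (1181 and 1043 of them among the 2005 and 2053), 984 and 797 at an adjusted p under 0.01, 510 and 341 with an absolute log2 difference of at least 1, and 3387 and 3571 for reporters in place of genes. Fewer or more items pass by construction in the last 3. Quantile normalization gives every array the same spread of ratios. The deposited ratios had SDs of 0.368 to 0.741 in tMCAO and 0.230 to 0.258 in sham animals. By construction it narrows the widest arrays, which were tMCAO arrays, and widens the sham arrays. How much of the loss of calls this explains was not tested. Leaving out 1 array gave 1479 to 2710 higher and 1377 to 2943 lower genes, the highest both without tMCAO replicate 4. Under loess, the other table, centring, filters, the brightest reporter, the variance models, array weights and ratios against 0 the counts stayed within 1.5 times. Replicate numbers carried no stated pairing, same-numbered animals deviated together at r = -0.06 to 0.06 across genes and no sham array correlated best with its own number; with the replicate block 1637 genes were higher and 1565 lower, and 16 and 8 lists, and the calls of Bnip3, Cd8a, Vcam1 and Uqcrc2 ended. Camera called 0 and 0 lists with an estimated correlation, and 0 and 0 without tMCAO replicate 4 as well (lowest adjusted p 0.052); leaving out 1 array at the preset correlation gave 15 to 16 higher and 7 to 8 lower lists. Fry did not call the cytokine, lymphocyte and cholesterol lists. Quantile normalization lost the endoplasmic reticulum stress, cytokine, lymphocyte and growth factor lists and 15 named genes: Klf4, Hspb1, Hspb8, Trib3, Ddit3, Bnip3, Prdx1, Il1r2, Cd8a, Sele, Ugt8, Sox10, Sdha, Uqcrc2 and Polr2a. Against 0 the microglia, mural and cholesterol lists and Egr4, Ccl3, Vcam1 and Polr2a were lost, with the brightest reporter the cholesterol list, Ndrg1, Uqcrc2 and Fdps, and by an ordinary t-test Neurod1, Bnip3, Cd2, Cd8a, Sele, Vcam1, Aqp1, Sox10, Rasd2, Uqcrc2 and Polr2a. Of 1749 other values of named genes 1620 kept their direction and side of the threshold, 128 lost the call and 1 reversed. Centring and the log2 of intensity 2 over intensity 1 gave 80 of the kept values each, nearly by construction. The median ratio of each array was already 0, and the deposited ratios are that same quotient.

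Directions reversed for Aqp1 against 0 (-0.023), and, for lists never called in the main test, by camera for heat shock genes after quantile normalization (median -0.14), without tMCAO replicate 4 and likewise with an estimated correlation (median 0.072 each; 0.065 to 0.166 over the arrays left out), for immediate early genes against 0 (median 0.15) and for choroid plexus markers without tMCAO replicate 1 (median -0.087; up to 0.29 over the arrays left out). The cause was not tested. Heat shock and immediate early lists were called in 1 setting each, higher against 0 (adjusted p = 0.0262) and lower after quantile normalization (0.00848). Dim signal limits small differences: 21.9% of genes had a sham intensity under 0.1, and no signal over background was available to these tests. Sprr1a and Gusb, at sham intensities of 0.089 and 0.0825, were among these genes.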

Other observations

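The test of an equal neuronal loss was chosen after the result was seen; the tests of blank cells and of other splits were chosen before.

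Named genes left a part of the response out. Of 7030 tested reporters without a gene name 745 were higher and 924 lower after tMCAO. For the sham animals against the pool, limma called 0 of 10977 genes above or below a sham ratio of 0, with 1797 at an unadjusted p under 0.05. Among members of the fixed lists that had no call, all named after their values were seen, the neuropeptide gene Tac1 had a log2 difference of 1.09 where 9 other striatal markers fell, and the homeostatic microglia marker Tmem119 had a difference of -0.06 where Cx3cr1, Laptm5 and 4 more markers rose. The neutrophil genes S100a9 and S100a8 had differences of 1.80 and 1.60 without passing the threshold. Their ratios were -0.81 and -0.74 in tMCAO replicate 4 and 1.91 to 3.23 in the other tMCAO animals, and 1.61 and 1.76 in sham replicate 1. Without tMCAO replicate 4, S100a9 (2.66, adjusted p = 0.0069), S100a8 (2.42, 0.0112) and Tac1 (1.59, 0.000245) passed the threshold, and without any other 1 array the 3 genes did not (adjusted p = 0.0826 to 0.363). S100a8 was dim, with intensities of 0.03 to 0.17 in sham animals.

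A hypothesis was that neuronal genes fell because neurons were lost, each transcript to the same degree. The SD of the 16 pan-neuronal members' log2 differences (those read on all 8 arrays) was 0.358, against 0.159 from the spread between animals, a factor of 2.26. Vamp2 fell by 0.44 on the log2 scale and Rab3a, dim at mean intensities of 0.065 in tMCAO and 0.1325 in sham cortex, by 1.72. An equal loss seen through reporters of equal response would not give that; transcripts shared with other cells and reporters with different background could, and were not tested.

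Blank cells were found mainly among bright reporters: 83.4% of the missing ratios lay in the brightest 1% of reporters, 534 of 1896 cells there against 106 of 186976 elsewhere. Values left out at high signal are a candidate explanation. A gene that rose to the top of the scale could therefore drop out: 8 of the 57 untested genes had sham values and no tMCAO value, among them Hspa1a and the related Hspa8, and 25 had tMCAO values and no sham value. The direction of change of these genes stays unknown here.

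Other splits of the 8 arrays into 4 and 4 were run to ask whether chance could give such counts. Of 35 splits 1, the real one, called as many as 4058 genes, and the highest of the others called 0. Every other split mixed tMCAO and sham arrays, so a real difference would widen the spread within its groups and lower its calls. These splits therefore cannot decide whether chance could give the count of genes. For lists, 6 of 35 splits called at least the 24 of the real one, and the highest other called 26. The 5 others each kept 3 of the 4 tMCAO arrays together and could carry much of a real difference. The count of lists did not set the real split apart, and these splits cannot decide on chance there either.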
